A study of Mus musculus with 36 samples.

How the data were processed

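Gene expression was measured with one-colour arrays hybridised with Cy5-labelled RNA from brain, heart, kidney and liver of female mice carrying a luciferase transgene. Each tissue was represented by 3 groups of 3 arrays, namely mock mice, mice given bacterial lipopolysaccharide (LPS), and mice given LPS followed by genipin, an iridoid compound from gardenia fruit. The 36 arrays thus formed 12 groups. Per the labels' protocols, LPS was injected into the peritoneal cavity at 4 mg/kg, genipin followed 10 min later, tissues were taken 4 h later, and 5 µg of RNA was labelled. The series description lists 25 mice in 5 treatment groups of 5 mice, with genipin at 1, 10 or 100 mg/kg. The genipin dose of the arrayed mice is not given in the sources used here, nor is whether the 3 arrays of a group came from separate mice.

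The deposited values are intensities on the linear scale, normalized by the authors within each tissue. They ranged from 9.46 to 65491.9 (16-bit limit 65535). The 9 arrays of a tissue held nearly the same sorted values, as quantile normalization within a tissue produces. Levels were thus not compared between tissues. Per the submitters' processing notes limma was used, with no version or role. Background correction, scanner software and the probe filter are not given in the sources used here. Of 18183 probes, 3680 were missing from all 9 brain arrays, 4640 from heart, 4919 from kidney and 6304 from liver, and no probe was missing from only part of a tissue's arrays. The missing probes were dimmer in the other tissues than the measured ones, with median intensities of 594 against 1575 for brain, 779 against 1807 for heart, 620 against 1687 for kidney and 633 against 2148 for liver.

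For this re-analysis the intensities were raised to a floor at their 5th percentile, 263, and converted to log2. A gene whose arrays of a group all lay at the floor, or all at or above an intensity of 60000, where the scanner saturates, was given a bound ("at least") in place of a fold, and no fold was given where both groups lay at the same limit. Medians of gene lists hold such genes at their bound. Probes were matched to gene symbols through the platform annotation. Of these, 14817 carried 1 symbol, none carried several and 3366 carried none. The symbol was current in the reference gene table (assembly GRCm38.p6) for 12468 probes, was updated through a synonym for 2318 and stayed as given for 31. Of the 12394 genes, 2079 had more than 1 probe, and the probe with the highest mean over all 36 arrays was taken. This left 10224 genes in brain, 9669 in heart, 9614 in kidney, 8641 in liver and 6861 measured in all 4 tissues.

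Comparisons were LPS against mock, LPS+genipin against LPS, and LPS+genipin against mock, in that order of subtraction. Each tissue's 9 arrays were fitted with group means in limma 3.58.1 (R 4.3.3), and moderated p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. All p-values were two-sided. A fit over all 36 arrays gave an F test of whether a comparison differed among the 4 tissues, the mean over the tissues, and each tissue's difference from the mean of the other 3. The test of a gene list was camera from limma, which compares its members with all other genes, with a preset correlation of 0.01 and again with an estimated correlation; 249 such tests were adjusted together, of which 121 passed with the preset and 80 with the estimated correlation, all 80 among the 121. Tissue differences of lists made a second family of 144 tests, of which 34 passed (22 with the estimated correlation).

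The change with genipin along the LPS response was measured with genes picked in other arrays than those compared. For each LPS array, genes at least 2-fold from the mock mean in that array were taken, and the median over them of the difference between the LPS+genipin mean and the mean of the other LPS arrays was found, signed so that a negative value points back toward mock. The 3 medians were averaged. Simulated data in which genipin did nothing gave means of 0.0018, −0.00067, 0.00031 and 0.00021 in brain, heart, kidney and liver over 20 simulations. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

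The 21 gene lists and 21 cell-type marker lists, the comparisons and the rule for named genes were chosen before the data were examined. The gene lists covered chemokines, cytokines, NF-kB feedback and target genes, interferon-stimulated genes, acute-phase proteins, LPS recognition and Toll-like receptor (TLR) signalling, endothelial activation and coagulation, glucocorticoid-responsive genes, immediate early genes, heat-shock proteins, NRF2 and antioxidant genes, the unfolded protein response and ATF4 targets, xenobiotic and bile acid metabolism, fatty acid oxidation and PPARA targets, oxidative phosphorylation, cholesterol synthesis, the circadian clock, the cell cycle, kidney tubule transporters, tubule injury markers, and cardiac stress and contractile genes. The marker lists covered neutrophils, monocytes and macrophages, T cells, B cells, red blood cells, endothelial cells, fibroblasts and pericytes, neurons, astrocytes, microglia, oligodendrocytes, choroid plexus, hepatocytes, cardiomyocytes, skeletal muscle, adipocytes, proximal tubule, distal nephron, podocytes, pancreatic acinar cells, and lung and airway. Longer marker lists of fat, atrial muscle, skeletal muscle, choroid plexus and thalamus were added after the data had been seen. For each LPS against mock and LPS+genipin against LPS comparison, the rule named the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold whose arrays did not overlap, up to 3 members of each list past the threshold, and a panel of 12 genes (Tnf, Il1b, Il6, Ccl2, Cxcl1, Cxcl10, Nfkbia, Tnfaip3, Icam1, Lcn2, Saa3 and Ucp2). The panel was also followed in LPS+genipin against mock. For tests over all tissues it named the 6 genes with the smallest p.

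The tests were tried on simulated data in which 200 genes of the real arrays' means and spreads were changed. Of 50 genes changed 1.25-fold, 24% were recovered in brain, 36% in heart, 42% in kidney and 36% in liver. For 1.5-fold changes the shares were 72, 60, 74 and 70%, for 2-fold 96, 90, 98 and 96%, and for 4-fold 98, 100, 100 and 98%. False calls made up 7.64, 3.38, 5.99 and 5.66% of all calls. Of 100 genes changed 2-fold in liver only, 94% were found to differ among tissues, against 0% of 100 changed 2-fold alike in all 4. A true signed change of −50% was found as −50.3, −50.9, −51.4 and −51.5%.

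Alternatives covered another quantile normalization within tissues, centring of arrays on their medians, a floor at the 25th percentile (620) or none, only the brighter 50% of genes, every probe, the mean of a gene's probes, a 2-fold threshold, limma with trend and robust variance, 1 fit over all 36 arrays, the replicate number as a fixed or random block, an estimated correlation for lists, genes at least 4-fold from mock for the signed change, and each array left out. Same-numbered brain arrays of LPS and LPS+genipin deviated together (correlations 0.118, 0.193 and 0.176). This pairing comes from the values, not the labels, and results that blocking on it changed are given "with the block". No array was left out of the comparisons, and every column was used.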

Results

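Transcript levels were measured on 36 arrays of mouse brain, heart, kidney and liver, 3 per group. Comparisons ask how each organ responded to LPS, a bacterial outer membrane component driving acute inflammation, and how genipin after LPS altered that response. Median intensities were nearly equal among the 9 arrays of a tissue, at about 2097 in brain, 1464 in heart, 1811 in kidney and 1253 in liver. Correlations between arrays of a group lay between 0.984 and 0.998, and the median standard deviation between them was 0.0591 to 0.140 on the log2 scale. Nothing in the labels says whether the 3 arrays are separate mice, so the p-values measure only the spread between these arrays. Gene values below are log2 differences between group means ± SE, each over 3 arrays per group, with limma p-values adjusted over all genes of the tissue.

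Of the 12 panel genes, Icam1, Lcn2 and Nfkbia were measured in all 4 tissues, and Ucp2, which encodes a mitochondrial uncoupling protein, in none. In assembly GRCm38.p6, Lcn2 lies on chromosome 2 from 32384637 to 32387739, Icam1 on chromosome 9 from 21015940 to 21028814 and Nfkbia on chromosome 12 from 55489409 to 55492647. All 3 rose with LPS in each tissue. Icam1, a leukocyte adhesion molecule, rose by 4.13 ± 0.06 in brain, 4.19 ± 0.10 in heart, 4.15 ± 0.05 in kidney and 3.13 ± 0.07 in liver. Nfkbia, which encodes the NF-kB inhibitor IkBa, rose by 1.47 ± 0.07, at least 1.80, 1.47 ± 0.08 and 1.19 ± 0.08.

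In brain, LPS raised the siderophore-binding protein gene Lcn2 184-fold (7.53 ± 0.08). The LPS co-receptor Cd14 rose 17.4-fold (4.12 ± 0.08), the interferon-induced genes Ifi47, Rsad2 and Gbp2 rose by 4.08 ± 0.08, 4.04 ± 0.10 and 3.87 ± 0.07, and the cholesterol hydroxylase gene Ch25h by 3.96 ± 0.06. The microglial genes Cx3cr1, P2ry12 and Tmem119 fell, by −2.27 ± 0.07, −1.53 ± 0.05 and −1.37 ± 0.13. The endothelial receptors Tek and Kdr fell by −1.86 ± 0.10 and −1.43 ± 0.14. The other large falls were those of muscle transcripts, with Mylpf at −7.29 ± 0.10, Tnnc2 at −4.95 ± 0.08, Acta1 at −4.19 ± 0.06, Tnnt3 at −4.01 ± 0.11 and Mss51 at −3.67 ± 0.06. Ttr, the thyroxine carrier made by choroid plexus, was at least 22.0-fold lower.

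Of 24 interferon-stimulated genes measured in brain, 23 rose and 1 did not pass (24 rose adjusted over the list alone), with a median of 1.70 (camera adjusted p = 5.03e-20). Among NF-kB feedback and target genes 12 of 13 rose (median 1.05, adjusted p = 1.19e-09), with Birc3 at 2.04 ± 0.08 and Tnfaip3, a brake on NF-kB, at 2.01 ± 0.08. All 6 acute-phase genes rose (median 1.48, adjusted p = 1.17e-07), among them the copper carrier Cp by 2.30 ± 0.06. Of 14 genes of LPS recognition and TLR signalling 8 rose and 6 did not pass (10 rose adjusted over the list alone), with adjusted p = 1.80e-05, and Tlr2 was at least 8.78-fold higher. Chemokines rose in 5 of 6 members (adjusted p = 0.000252), with Ccl12 at least 10.5-fold higher. Endothelial activation and coagulation genes rose in 6 of 8 and fell in 1 (adjusted p = 0.000228), and glucocorticoid-responsive genes rose in 7 of 11 (adjusted p = 0.000451). Of the 6 genes listed as tubule injury markers 5 rose (adjusted p = 2.58e-06), led by Lcn2, the matrix phosphoprotein Spp1 (3.20 ± 0.07) and the metalloproteinase inhibitor Timp1 (at least 6.05-fold). These 8 lists also passed with an estimated correlation. Immediate early genes went both ways, with 10 of 18 higher and 6 lower (adjusted p = 0.188), Zfp36 rising by 2.53 ± 0.10 and Egr2 falling by −1.57 ± 0.07.

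The other brain lists did not pass with LPS. These were cytokines (2 of 5 higher, adjusted p = 0.28), heat-shock proteins (2 of 8 lower, 0.669), NRF2 and antioxidant genes (3 of 13 higher, 0.596) and the unfolded protein response (1 higher and 1 lower of 12, 0.934). The others were xenobiotic metabolism (0 of 4, 0.242), fatty acid oxidation (2 higher and 1 lower of 10, 0.537) and oxidative phosphorylation (1 higher and 2 lower of 25, 0.805). Cholesterol synthesis (3 of 12 higher, 0.397), the circadian clock (2 of 14 higher, 0.596), the cell cycle (2 higher and 1 lower of 5, 0.529), tubule transporters (3 of 4 lower, 0.0531) and cardiac genes (1 higher and 1 lower of 5, 0.678) did not pass either. Of the 25 oxidative phosphorylation genes 7 (9 with genipin) lay within limits in every tissue, so counts may miss changes. The NRF2 and unfolded protein response lists had medians of −0.03 and −0.02 but positive means (0.08 and 0.02) and a positive test direction. Adjusted over the list alone, 2 NRF2 genes, 1 clock gene and 3 cell cycle genes were higher, 1 oxidative phosphorylation gene was lower, and other counts were equal.

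Among cell-type markers of brain, 5 of 5 microglial markers fell (median −1.37), 6 of 8 endothelial markers fell and Cdh5 rose by 1.22 ± 0.08, and 4 of 8 monocyte and macrophage markers fell with 1 higher. The oligodendrocyte markers Mobp, Cnp and Mog rose (3 of 5), as did 3 of 5 astrocyte markers with 1 lower. Of 6 neutrophil markers S100a8 and S100a9 rose, by 1.42 ± 0.09 and 1.27 ± 0.08, and Csf3r fell. Skeletal muscle markers fell in 3 of 4 (median −4.10), and muscle transcripts lay at a median of 13.7 to 13.8 in the mock brains against 8.66 to 8.79 in the LPS brains. Fibroblast and pericyte markers were higher in 1 and lower in 2 of 8, choroid plexus markers higher in 1 and lower in 1 of 4, hepatocyte markers higher in 2 and lower in 1 of 3, and neuronal markers lower in 1 of 6. Single markers of proximal tubule (Slc22a6) and pancreatic acinar cells (Ctrb1) were lower and that of distal nephron (Calb1) higher. No marker passed among B cells (1 measured), red blood cells (2), cardiomyocytes (1) and podocytes (1), and none was measured for T cells, adipocytes or lung. Adjusted over the list alone, 4 neutrophil markers were higher and 2 lower, and 2 macrophage markers were higher. The brain test called 3460 of 10224 genes, 1675 higher and 1785 lower, and 243 of them changed at least 2-fold (164 higher). Arrays of the groups did not overlap for 47.8% of genes, where chance gives 10%.

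In heart, LPS raised the haptoglobin gene Hp 212-fold (7.72 ± 0.10). The chemokines Cxcl1 and Ccl2 and Lcn2 were at least 118-fold, 64.0-fold and 70.6-fold higher, and Cxcl9 rose by 5.21 ± 0.07. The Notch target Hey1 (−2.53 ± 0.11), the adhesion molecule Pcdh12 (−2.40 ± 0.07), the phosphatase Ptprb (−2.20 ± 0.08), Egfl7 (−1.93 ± 0.08) and the angiopoietin receptor Tek (−1.86 ± 0.11) fell. The chemokine Cxcl12 fell by −2.22 ± 0.13, the lipid transporter gene Abca8a by −2.32 ± 0.09 and Dok4 by −2.21 ± 0.09. The LPS hearts also differed from mock in transcripts of fat, with Cfd higher by 5.62 ± 0.07 and Adipoq by 4.97 ± 0.11, and of atrial muscle, with the atrial light chain Myl7 at least 50.6-fold higher.

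Of 29 interferon-stimulated genes in heart 27 rose (28 adjusted over the list alone; median 2.47, camera adjusted p = 6.64e-23), among them Gbp5 (4.83 ± 0.20), Ifi47 (4.75 ± 0.14) and Gbp3 (4.40 ± 0.08). NF-kB target genes rose in 12 of 14 (13 adjusted over the list alone; adjusted p = 1.52e-10), chemokines in 7 of 9 (8 adjusted over the list alone; 2.72e-08) and acute-phase genes in 7 of 7 (median 4.28, 9.13e-10), with the LPS-binding protein Lbp at 4.52 ± 0.07. Immediate early genes rose in 18 of 21 and fell in 1 (3.39e-10), with the transcription factors Fos at 3.06 ± 0.09 and Egr1 at 2.80 ± 0.09. TLR signalling rose in 8 of 15 and fell in 2 (4.01e-05), glucocorticoid-responsive genes rose in 7 of 12 (0.000404), and the tubule injury list rose in 5 of 5 (5.19e-07) through genes such as Timp1 (4.93 ± 0.11) and the adhesion molecule Vcam1 (3.44 ± 0.08). Those lists passed with an estimated correlation too. Endothelial activation genes were higher in 6 of 8 and lower in 1 (2 lower adjusted over the list alone; adjusted p = 0.000756), which became adjusted p = 0.101 with an estimated correlation. Cytokines were higher in 3 of 7 and lower in 1 (adjusted p = 0.0178), with adjusted p = 0.154 with an estimated correlation, and the granulocyte growth factor Csf3 rose by 4.08 ± 0.08 while Tnf stood at 0.32 ± 0.19 (adjusted p = 0.19).

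The other heart lists did not pass with LPS. They were heat-shock proteins (4 of 8 lower, adjusted p = 0.358), NRF2 genes (4 higher and 3 lower of 15, 0.937), the unfolded protein response (4 higher and 1 lower of 13, 0.329), xenobiotic metabolism (2 higher and 1 lower of 7, 0.177), fatty acid oxidation (1 higher and 4 lower of 15, 0.515) and oxidative phosphorylation (4 of 25 lower, 0.301). Cholesterol synthesis (2 of 9 higher, 0.227), the clock (2 higher and 6 lower of 13, 0.224), the cell cycle (4 higher and 1 lower of 11, 0.21), tubule transporters (0 of 4, 0.988) and cardiac stress and contractile genes (3 of 12 lower, 0.475) completed them. The heat-shock list had a median of −0.17 and a mean of 0.10, the NRF2 list −0.07 and 0.03, and the transporter list a median of −0.07 with a positive test direction. Adjusted over the list alone, 3 fatty acid oxidation genes, 8 clock genes and 1 cardiac gene were lower and other counts were equal. Ppargc1a fell by −1.65 ± 0.09, and the clock genes Per3 and Dbp fell by −1.24 ± 0.09 and −1.07 ± 0.09.

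Neutrophil markers rose in 4 of 4 in the LPS hearts (median 4.04), with Ltf at 4.42 ± 0.13, S100a9 at 4.05 ± 0.15 and S100a8 at 4.02 ± 0.06. Both adipocyte markers rose (median 5.29), and the median of 4 fat transcripts lay at 14.7 to 15.1 in the LPS hearts against 9.77 to 10.0 in mock. Of 6 cardiomyocyte markers Myl7 alone passed. Endothelial markers fell in 4 of 8, and hepatocyte markers in 2 of 2. Monocyte and macrophage markers were higher in 3 and lower in 2 of 9, fibroblast and pericyte markers higher in 3 and lower in 2 of 8, neuronal markers higher in 1 and lower in 1 of 4, and microglial markers higher in 1 and lower in 1 of 2. The single T cell marker (Cd3e), the single astrocyte marker (Aldh1l1), 1 of 3 B cell, 1 of 2 red blood cell and 1 of 3 oligodendrocyte markers rose, and 1 of 4 skeletal muscle and 1 of 2 podocyte markers fell. No marker passed for proximal tubule (1 measured), distal nephron (2), pancreatic acinar cells (1) or lung (1), and no choroid plexus marker was measured. Adjusted over the list alone, 4 macrophage, 2 B cell, 4 fibroblast and 2 oligodendrocyte markers were higher. The heart test called 4550 of 9669 genes, 1756 higher and 2794 lower, with 692 changed at least 2-fold (467 higher) and 54.1% of genes with non-overlapping arrays against 10% by chance.

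In kidney, LPS raised the neutrophil chemokine Cxcl1 172-fold (7.43 ± 0.07), Lcn2 at least 161-fold and the interferon-induced chemokine Cxcl10 at least 121-fold. The fibrinogen chains Fgb and Fgg rose 60.5-fold (5.92 ± 0.08) and at least 64.0-fold, the guanylate-binding protein gene Gbp5 by 6.08 ± 0.07, and Cd14 by 5.48 ± 0.05. The angiopoietin receptor Tek fell by −2.96 ± 0.06, Ptprb by −2.52 ± 0.07 and the endothelial proteoglycan Esm1 by −2.34 ± 0.08. Banp, Dleu7 and Gdf10 fell by −2.76 ± 0.07, −2.50 ± 0.09 and −2.48 ± 0.10, the phosphatase Dusp9 by −2.68 ± 0.08 and the inducible chaperone Hspa1b by −1.91 ± 0.05.

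All 27 interferon-stimulated genes rose in kidney (median 3.71, camera adjusted p = 3.95e-22), as did all 18 immediate early genes (median 1.92, 3.76e-13), all 11 acute-phase genes (median 4.46, 2.08e-10), all 10 chemokines (median 3.45, 1.32e-09) and all 7 cytokines (median 1.06, 4.81e-05). Examples were Ifit2 (5.57 ± 0.09), Isg15 (5.44 ± 0.09), Fos (3.78 ± 0.05), the macrophage growth factor Csf1 (3.48 ± 0.06) and the death ligand Tnfsf10 (2.20 ± 0.06). NF-kB target genes rose in 14 of 16 (adjusted p = 3.05e-10), with Tnfaip3 at 4.29 ± 0.04. TLR signalling rose in 12 of 16 (1 more was lower adjusted over the list alone; 4.22e-06), glucocorticoid-responsive genes in 8 of 11 (0.000323) and tubule injury markers in 7 of 8 (0.000151). These lists passed with an estimated correlation. Endothelial activation genes were higher in 7 of 10 and lower in 2 (adjusted p = 0.00429, and 0.132 with an estimated correlation). The unfolded protein response list was higher in 7 of 12 and lower in 2 (adjusted p = 0.0102, and 0.0665 with an estimated correlation), with Chac1 at 1.99 ± 0.07 and the asparagine synthetase gene Asns at 1.62 ± 0.06. Xenobiotic metabolism genes were higher in 7 of 11 and lower in 1 (adjusted p = 0.0106, and 0.0791 with an estimated correlation).

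Kidney lists that did not pass with LPS were heat-shock proteins (2 higher and 4 lower of 9, adjusted p = 0.585), NRF2 genes (4 higher and 4 lower of 14, 0.503), fatty acid oxidation (5 higher and 1 lower of 15, 0.106) and oxidative phosphorylation (4 of 25 lower, 0 adjusted over the list alone, 0.698). Cholesterol synthesis (5 higher and 2 lower of 11, 0.301), the clock (5 higher and 6 lower of 12, 0.892), the cell cycle (3 higher and 1 lower of 9, 0.309), tubule transporters (1 higher and 5 lower of 16, 4 lower adjusted over the list alone, 0.599) and cardiac genes (1 higher and 2 lower of 3, 0.831) also did not. Other counts were equal adjusted over the list alone. The cholesterol list had a median of −0.02 with a mean of 0.11 and a positive test direction. Pdk4 rose by 3.47 ± 0.12, the clock gene Arntl by 1.47 ± 0.10, and Hlf fell by −1.41 ± 0.10.

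Of kidney cell-type markers, both neutrophil markers rose (S100a9 by 4.12 ± 0.17), as did 6 of 8 monocyte and macrophage markers with 1 lower, 3 of 3 adipocyte markers (median 0.59), 3 of 5 hepatocyte markers and 2 of 2 microglial markers. Fibroblast and pericyte markers were lower in 5 of 8 and higher in 2, endothelial markers lower in 4 of 8 and higher in 2, both red blood cell and both pancreatic acinar markers lower, choroid plexus markers lower in 2 of 3, and podocyte markers lower in 2 of 3. Of 5 proximal tubule markers Slc5a2 fell by −0.31 ± 0.07, and distal nephron markers were higher in 1 and lower in 1 of 5. Skeletal muscle markers were higher in 1 and lower in 2 of 3, the B cell and oligodendrocyte markers (1 each) were higher, and 1 of 2 astrocyte (1 more lower adjusted over the list alone) and 1 of 2 lung markers were higher. No T cell, neuronal or cardiomyocyte marker was measured. The kidney test called 6182 of 9614 genes, 2430 higher and 3752 lower, with 809 changed at least 2-fold (517 higher) and 69.1% of genes with non-overlapping arrays against 10% by chance.

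In liver, LPS raised Cd14 at least 48.3-fold, Tifa by 5.33 ± 0.11, Ccl5 by 5.31 ± 0.04, Serpina3g by 5.24 ± 0.08 and Gbp2 by 5.03 ± 0.07. Genes that fell included the bile acid synthesis gene Cyp7a1 17.7-fold (−4.14 ± 0.12), the nuclear receptors Nr1i3 (−2.18 ± 0.08) and Nr0b2 (−1.84 ± 0.10), the glucose-6-phosphatase gene G6pc (−1.92 ± 0.05) and Ddc (−3.46 ± 0.08). Arrdc3 fell 25.2-fold (−4.66 ± 0.08), Cnmd by −3.56 ± 0.20 and the vascular endothelial growth factor receptor Kdr by −3.48 ± 0.13, and Fam13a was at least 12.6-fold lower. The clock genes Dbp and Per3 fell by −2.57 ± 0.10 and −2.15 ± 0.10, and Hspa1b by −2.73 ± 0.10.

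Of 30 liver interferon-stimulated genes 29 rose (median 2.31, camera adjusted p = 9.20e-16), with Cmpk2 at 4.97 ± 0.09 and Ifit2 at 4.96 ± 0.09. All 14 NF-kB target genes rose (6.51e-08), immediate early genes rose in 13 of 16 (2.15e-06), chemokines in 7 of 9 (7.96e-06), TLR signalling genes in 9 of 14 (0.000151) and glucocorticoid-responsive genes in 9 of 12 (0.000464), with Ddit4 at 3.47 ± 0.06. Unfolded protein response genes rose in 9 of 12 and fell in 1 (median 0.59, adjusted p = 0.0018), with the chaperone Dnajb9 at 2.20 ± 0.07 and the transcription factor Atf4 at 1.70 ± 0.06. These 7 lists passed with an estimated correlation. Acute-phase genes rose in 8 of 17 and 9 did not pass (median 0.11, adjusted p = 0.00496, and 0.142 with an estimated correlation). Saturation capped some rises (Saa3 at least 31.6-fold, Lcn2 at least 7.80-fold), so their size is unknown. Cytokines were higher in 6 of 9 (adjusted p = 0.00227, and 0.133 with an estimated correlation), with Il1b at 3.36 ± 0.07 and Il6 at least 6.29-fold higher.

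Oxidative phosphorylation genes fell in 14 of 25 in the LPS livers and none rose (median −0.23, adjusted p = 0.0116, and 0.0614 with an estimated correlation), with the complex subunits Sdhb at −0.63 ± 0.07 and Ndufs3 at −0.60 ± 0.06. Xenobiotic and bile acid genes fell in 13 of 23 and rose in 3 (14 and 4 adjusted over the list alone), with adjusted p = 0.0419, and 0.117 with an estimated correlation. Endothelial activation genes were higher in 5 of 6 and lower in 1 (adjusted p = 0.0228, and 0.336 with an estimated correlation), and tubule injury markers higher in 5 of 7 (adjusted p = 0.00598, and 0.103 with an estimated correlation). Lists that did not pass were heat-shock proteins (3 higher and 5 lower of 9, 0.343), NRF2 genes (3 higher and 6 lower of 13, 0.522) and fatty acid oxidation (3 higher and 4 lower of 14, 0.761). Others were cholesterol synthesis (1 higher and 5 lower of 11, 0.498), the clock (1 higher and 6 lower of 9, 0.067), the cell cycle (3 of 5 lower, 0.298) and tubule transporters (2 higher and 1 lower of 6, 0.559). The fatty acid list had a median of −0.03 and a negative test direction with a mean of 0.07. Both cardiac genes measured rose, too few for a test. Adjusted over the list alone, 1 transporter gene was higher and 0 lower, and other counts were equal.

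Liver neutrophil markers rose in 3 of 3 (median 4.27), with S100a8 at 4.75 ± 0.10 and S100a9 at 4.27 ± 0.12. Monocyte and macrophage markers split, with 3 of 10 higher, among them Marco (2.64 ± 0.05), and 5 lower, among them the mannose receptor Mrc1 (−1.50 ± 0.05). Endothelial markers were higher in 3 and lower in 4 of 8, fibroblast and pericyte markers lower in 4 of 5 (median −0.48), and hepatocyte markers higher in 1 (Apob) and lower in 1 (G6pc) of 8. The microglial marker Aif1 was lower, single B cell, podocyte and lung markers and 1 of 2 red blood cell markers were higher, and neuronal (2 measured), skeletal muscle (3) and pancreatic acinar (2) markers had 1 higher and 1 lower each. Of 2 distal nephron markers 1 was higher (0 adjusted over the list alone), no astrocyte (2) or oligodendrocyte (1) marker passed, and no T cell, choroid plexus, cardiomyocyte, adipocyte or proximal tubule marker was measured. The liver test called 5704 of 8641 genes, 2529 higher and 3175 lower, with 1350 changed at least 2-fold (691 higher) and 70.2% of genes with non-overlapping arrays against 10% by chance.

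**Figure D1:**
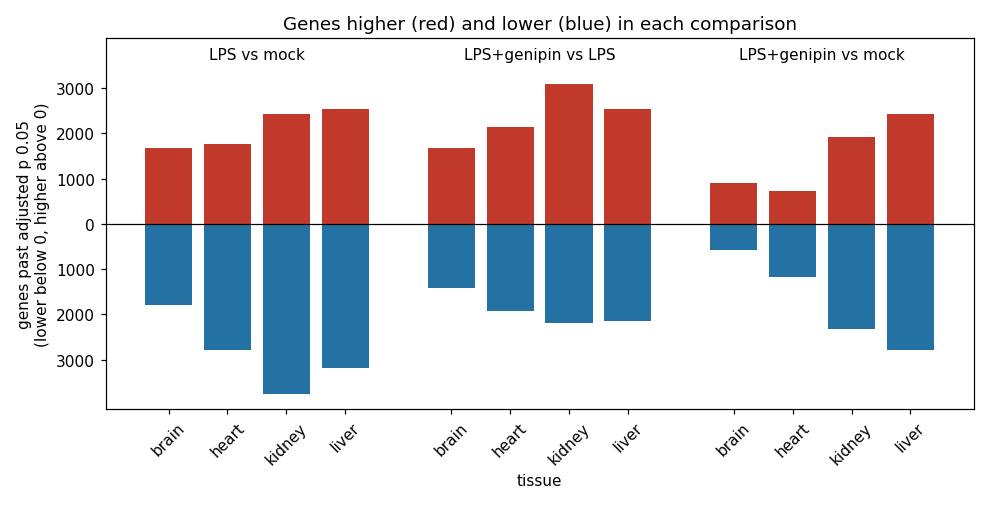
Number of genes past an adjusted p of 0.05 in each tissue and comparison, higher (red) above 0 and lower (blue) below 0 on the vertical axis. LPS against mock called from 3460 genes in brain to 6182 in kidney, and LPS+genipin against LPS from 3085 to 5262.

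Across the 4 tissues, 276 of 6861 shared genes rose with LPS in every tissue, against 18.3 for independent lists, and 255 fell in every tissue, against 47.8. All 22 interferon-stimulated genes measured in every tissue rose in all 4. The response differed among tissues for 5267 genes (76.8%), and 1458 genes passed in opposite directions in at least 2 tissues. Lcn2 rose by 7.53, 6.14, 7.33 and 2.96 in brain, heart, kidney and liver, the last 3 being bounds (F test adjusted p = 3.56e-25, on saturated values). Cmpk2 rose by 0.24 in brain against 3.15, 4.21 and 4.97 (3.16e-24). The acute-phase gene Serpina3n rose by 0.98, 4.28, 5.71 and 0.75, the second and last being bounds (3.56e-25), the inhibitory Fc receptor gene Fcgr2b rose in heart (3.13) and fell in liver (−2.14; 1.44e-24), and Arrdc3 rose in heart (1.05) and fell in liver (−4.66; 1.80e-24). The muscle gene Mylpf differed mainly through its −7.29 in brain (2.27e-28).

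Gene groups also differed in size between tissues. Interferon-stimulated genes rose most in kidney, by a median of 1.43 more than the mean of the other tissues (adjusted p = 3.85e-22), and least in brain, by 0.98 less (−0.98, 5.02e-14). Immediate early genes differed by 0.71 in kidney (3.22e-07) and −1.50 in brain (3.07e-07), and NF-kB targets by 0.75 (5.54e-05) and −0.63 (0.00151). Acute-phase genes also passed, in heart (0.00109), kidney (0.000235) and liver (2.99e-05), but all 5 that were tested lay at the floor or at saturation in at least 1 tissue, which leaves the size of their difference unknown. The unfolded protein response rose more in liver than elsewhere, by 0.69 (0.00106). These differences passed with an estimated correlation.

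With genipin after LPS, brain arrays had lower levels of LPS-raised genes than with LPS alone. Rsad2 fell by −3.43 ± 0.10, Gbp2 by −2.61 ± 0.07, Ifi47 by −2.38 ± 0.08, Timp1 by −2.56 ± 0.08, Tlr2 by −2.32 ± 0.12 and the lymphocyte receptor gene Crtam by −2.30 ± 0.07. Icam1 fell by −1.58 ± 0.06, Tnfaip3 by −1.65 ± 0.08, Nfkbia by −0.70 ± 0.07 and Lcn2 by −0.69 ± 0.08. The microglial genes Cx3cr1 and P2ry12 rose by 1.42 ± 0.07 and 1.05 ± 0.05, and Tek by 1.10 ± 0.10. The largest rises were those of Ttr, at least 22.1-fold, the transcription factors Tcf7l2 (3.35 ± 0.09) and Zfhx3 (2.23 ± 0.10), Ecrg4 (2.36 ± 0.10) and Kl (2.25 ± 0.08), and Jak2 was at least 5.29-fold higher (2.40 ± 0.64). Of these, Ttr, Ecrg4 and Kl are abundant in choroid plexus and Tcf7l2 and Zfhx3 in thalamus.

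Of 24 brain interferon-stimulated genes 21 fell (22 adjusted over the list alone; median −1.23, camera adjusted p = 1.02e-19), of 13 NF-kB targets 11 fell (median −0.71, 1.08e-07), and of 6 chemokines 5 fell (0.000861), with Ccl9 at −1.07 ± 0.09. These passed with an estimated correlation, chemokines not with the block (adjusted p = 0.0689 with both). Acute-phase genes fell in 2 of 6 (4 adjusted over the list alone; adjusted p = 0.0155, and 0.268 with an estimated correlation), TLR genes in 6 of 14 (adjusted p = 0.00725, and 0.0588 with an estimated correlation) and tubule injury markers in 4 of 6 (adjusted p = 0.00874, and 0.141 with an estimated correlation). Tubule transporters were higher in 2 of 4 (adjusted p = 0.0218, and 0.101 with an estimated correlation), both of them, Slc27a2 and Slc22a8, solute carriers also present in brain. Immediate early genes were lower in 10 of 18 (9 with the block) and higher in 4 (0.111). Endothelial activation genes were lower in 4 of 8 and higher in 2 (0.0856). The unfolded protein response was lower in 4 of 12 (2 with the block, 0.0737). Cytokines were lower in 2 of 5 (0.224) and glucocorticoid-responsive genes in 3 of 11 with 1 higher (0.337). Cholesterol synthesis (4 of 12 higher, 0.225), fatty acid oxidation (2 of 10 higher, 0.26), NRF2 genes (1 higher and 1 lower of 13, 2 lower with the block, 0.69), oxidative phosphorylation (1 higher and 2 lower of 25, 0.613), the cell cycle (1 higher and 1 lower of 5, 0.761), cardiac genes (1 of 5 lower, 0.357), heat-shock proteins (0 of 8, 0.933), xenobiotic genes (0 of 4, 0.358) and the clock (0 of 14, 0.653) did not pass. The cell cycle list had a median of 0.02 and a mean of −0.07, and the heat-shock list a median of 0.01 with a negative test direction. With adjustment over the list alone, 1 cytokine was higher, 5 endothelial activation and 5 unfolded protein response genes were lower, and other counts were equal.

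Microglial markers rose in 5 of 5 (median 0.74) and choroid plexus markers in 4 of 4 (median 1.01) in the LPS+genipin brains. Oligodendrocyte markers rose in 4 of 5 and macrophage markers in 3 of 8. Endothelial and fibroblast markers each rose in 4 of 8 (3 for fibroblasts with the block) and fell in 1. Of the hepatocyte markers Ttr and Alb rose (2 of 3; with the block only 1, Alb having adjusted p = 0.0814). Skeletal muscle markers were higher in 2 and lower in 1 of 4, neuronal markers higher in 1 and lower in 1 of 6, astrocyte and neutrophil markers higher in 1 each (of 5 and 6; 2 astrocyte markers with the block). Lower were 1 of 2 red blood cell markers, the pancreatic acinar marker and the distal nephron marker. No B cell, cardiomyocyte, proximal tubule or podocyte marker passed (with the block 1 podocyte marker did). When adjusted within the list, 5 endothelial and 3 hepatocyte markers were higher. The test called 3085 genes, 1666 higher and 1419 lower, with 167 at least 2-fold (99 lower) and 39.1% non-overlapping against 10% by chance.

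In heart, genipin after LPS went with lower Hp (−4.60 ± 0.10), Timp1 (−3.71 ± 0.11), Cxcl9 (−3.65 ± 0.07), Vcam1 (−2.23 ± 0.08), Csf3 (−1.85 ± 0.08) and Fos (−1.89 ± 0.09). Icam1 fell by −1.11 ± 0.10 and Ccl2 by −0.89 ± 0.05, and Nfkbia, Cxcl1 and Lcn2 fell at least 1.36-fold, 1.60-fold and 1.27-fold. Genes that rose included the retinol-binding protein gene Rbp7 (2.19 ± 0.09), the adhesion receptor Adgrl4 (1.82 ± 0.10), the Z-disc protein gene Sorbs2 (1.78 ± 0.06), the potassium channel subunit Kcnip2 (1.73 ± 0.15), Itpripl1 (1.81 ± 0.12), Tspan13 (1.74 ± 0.15), Egfl7 (1.43 ± 0.08) and Tek (1.08 ± 0.11). Tnf was higher by 0.56 ± 0.19 (adjusted p = 0.043), with overlapping arrays. The fat and atrial transcripts that stood out in the LPS hearts fell by the largest amounts, with Myl7 and the atrial light chain Myl4 at least 91.6-fold and 24.9-fold lower and Cfd, the gluconeogenic gene Pck1 and Adipoq at −5.69 ± 0.07, −5.36 ± 0.17 and −4.95 ± 0.11.

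Of 29 heart interferon-stimulated genes 26 fell (median −1.83, camera adjusted p = 1.89e-18), with Ifi47 at −2.42 ± 0.14 and Ifit3 at −2.35 ± 0.10. Immediate early genes fell in 17 of 21 (19 adjusted over the list alone; 2.11e-09), NF-kB targets in 11 of 14 (3.85e-06) and acute-phase genes in 6 of 7 (7 adjusted over the list alone; 8.79e-06). Chemokines fell in 8 of 9 (1 more higher adjusted over the list alone; 2.91e-05), tubule injury markers in 5 of 5 (3.89e-05) and TLR genes in 8 of 15 (9 lower and 2 higher adjusted over the list alone; 0.00157). These passed with an estimated correlation. Endothelial activation genes fell in 5 of 8 (adjusted p = 0.000323, and 0.083 with an estimated correlation). Lists that did not pass were the cell cycle (6 higher and 1 lower of 11, 0.0643), fatty acid oxidation (6 of 15 higher, 0.0904), oxidative phosphorylation (6 of 25 higher, 0.0925) and xenobiotic genes (1 higher and 3 lower of 7, 0.0975). Also short of the threshold were the clock (7 higher and 2 lower of 13, 0.138), the unfolded protein response (3 higher and 6 lower of 13, 0.139), cholesterol synthesis (1 higher and 2 lower of 9, 0.203) and heat-shock proteins (2 of 8 lower, 0.322). The same holds for cytokines (1 higher and 2 lower of 7, 0.358), tubule transporters (3 higher and 1 lower of 4, 0.522), cardiac genes (2 of 12 lower, 0.686), glucocorticoid-responsive genes (3 higher and 3 lower of 12, 0.831) and NRF2 genes (4 of 15 higher, 0.835). The glucocorticoid list had a median of 0.01 against a mean of −0.12, the NRF2 list −0.07 against 0.06, and the cardiac list a mean of 0.02 with a negative test direction. By the list-only adjustment, 5 oxidative phosphorylation, 8 clock and 4 glucocorticoid-responsive genes were higher, 4 xenobiotic genes were lower, and other counts were equal.

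In the LPS+genipin hearts neutrophil markers fell in 4 of 4 (median −1.04), both adipocyte markers fell (median −5.32), and the 4 fat transcripts lay at 9.68 to 9.74, beside the mock hearts. Endothelial markers rose in 5 of 8 (median 0.52) and hepatocyte markers in 2 of 2. Macrophage markers were higher in 3 and lower in 1 of 9, fibroblast markers higher in 1 and lower in 2 of 8, neuronal markers higher in 1 and lower in 2 of 4. Both red blood cell markers, 2 of 3 oligodendrocyte markers, 1 of 3 B cell, 1 of 2 microglial, 1 of 6 cardiomyocyte and the astrocyte and pancreatic acinar markers were lower. The proximal tubule marker and 1 of 4 skeletal muscle markers rose, distal nephron markers split with 1 higher and 1 lower, and T cell, podocyte and lung markers did not pass. Within single lists, 1 microglial and 2 muscle markers were higher. The test called 4053 genes, 2135 higher and 1918 lower, with 479 at least 2-fold (353 lower) and 52.5% non-overlapping against 10% by chance.

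In kidney, Hesx1 (−3.17 ± 0.10), Fgb (−3.07 ± 0.08), Ifit2 (−2.83 ± 0.09), Cd14 (−2.67 ± 0.05) and the acute-phase gene Lrg1 (−2.39 ± 0.07) fell most with genipin after LPS. Icam1 fell by −0.93 ± 0.05, Cxcl10 by −0.89 ± 0.04, Tnfaip3 by −0.46 ± 0.04 and Cxcl1 by −0.37 ± 0.07, Lcn2 was at least 1.51-fold lower, Nfkbia stood at −0.20 ± 0.08 (adjusted p = 0.073) and Il1b rose by 0.39 ± 0.07. Tek rose by 2.18 ± 0.06, Cyp27b1, which activates vitamin D, by 2.28 ± 0.08, Mgl1 by 2.49 ± 0.11, Exoc3l2 by 2.12 ± 0.06, Abca8a by 2.02 ± 0.05 and the antioxidant gene Srxn1 by 1.24 ± 0.05. Mylpf, a muscle gene, rose by 2.68 ± 0.05.

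All 27 kidney interferon-stimulated genes fell (median −1.44, camera adjusted p = 1.45e-19). NF-kB targets fell in 14 of 16 (15 adjusted over the list alone; 1.21e-07), with Birc3 at −1.52 ± 0.06, immediate early genes in 15 of 18 with 2 higher (9.42e-07), acute-phase genes in 9 of 11 (3.60e-05) and TLR genes in 9 of 16 (0.000112). These passed with an estimated correlation. Chemokines fell in 7 of 10 and rose in 2 (adjusted p = 0.00421, and 0.0617 with an estimated correlation), and cytokines fell in 6 of 7 with 1 higher (adjusted p = 0.00496, and 0.0572 with an estimated correlation). NRF2 genes were higher in 7 of 14 and lower in 1 (adjusted p = 0.0381, and 0.12 with an estimated correlation), and the unfolded protein response lower in 7 of 12 and higher in 2 (adjusted p = 0.0454, and 0.121 with an estimated correlation). Lists that did not pass were cholesterol synthesis (7 higher and 2 lower of 11, 0.14), the clock (7 higher and 2 lower of 12, 0.177), fatty acid oxidation (1 higher and 3 lower of 15, 0.182) and cardiac genes (2 of 3 higher, 0.188). Others were endothelial activation (3 higher and 5 lower of 10, 0.203), tubule injury markers (2 higher and 4 lower of 8, 0.242) and heat-shock proteins (4 higher and 1 lower of 9, 0.25). Glucocorticoid-responsive genes (2 higher and 4 lower of 11, 0.463), oxidative phosphorylation (0 of 25, 0.613), tubule transporters (3 higher and 3 lower of 16, 0.613), xenobiotic genes (3 higher and 3 lower of 11, 0.678) and the cell cycle (3 higher and 2 lower of 9, 0.772) did not pass either. On adjustment inside each list, 3 glucocorticoid-responsive and 8 clock genes were higher and other counts were equal.

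Kidney fibroblast and pericyte markers rose in 7 of 8 with genipin after LPS (median 0.83), with Col1a1 at 1.35 ± 0.09, as did 3 of 3 skeletal muscle markers (median 1.08), 3 of 3 adipocyte markers and 3 of 5 hepatocyte markers. Endothelial markers were higher in 3 and lower in 2 of 8, macrophage markers higher in 4 and lower in 4 of 8, and distal nephron markers higher in 2 and lower in 1 of 5. Of 2 astrocyte, 2 microglial (1 more lower adjusted over the list alone) and 3 choroid plexus markers 1 each was higher, and the B cell, oligodendrocyte, 1 of 2 red blood cell and 1 of 2 lung markers were lower. No neutrophil, proximal tubule, podocyte or pancreatic acinar marker passed. The test called 5262 genes, 3081 higher and 2181 lower, with 439 at least 2-fold (293 lower) and 61.8% non-overlapping against 10% by chance.

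In liver, interferon-stimulated genes fell most with genipin after LPS, with Ifit2 at −4.23 ± 0.09, Cmpk2 at −3.87 ± 0.09, Ifit3 at −3.81 ± 0.05, Isg15 at −3.30 ± 0.07 and Rsad2 at −3.29 ± 0.06, while Csta2 fell by −3.28 ± 0.43. The chaperone Hspa1b rose by 3.58 ± 0.10, the sulfiredoxin gene Srxn1 9.76-fold (3.29 ± 0.08), the glutathione synthesis gene Gclc 9.34-fold (3.22 ± 0.23), Foxq1 by 3.18 ± 0.06 and the tubulin gene Tubb2a by 3.13 ± 0.05. Fam13a was at least 8.42-fold higher. Of the panel, Il6 (−1.29 ± 0.08), Cxcl10 (−1.65 ± 0.07), Il1b (−0.83 ± 0.07), Tnfaip3 (−0.45 ± 0.05) and Nfkbia (−0.24 ± 0.08) fell, Cxcl1 was at least 1.16-fold lower, Icam1 rose by 0.67 ± 0.07, and Lcn2 and Saa3 were saturated in both groups.

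Of 30 liver interferon-stimulated genes 29 fell (30 adjusted over the list alone; median −1.46, camera adjusted p = 1.45e-19). NRF2 and antioxidant genes rose in 11 of 13 (median 0.96, 7.93e-06) and unfolded protein response genes fell in 8 of 12 (median −0.39, 0.00043), with Sdf2l1 at −1.16 ± 0.07; these passed with an estimated correlation. Heat-shock proteins rose in 9 of 9 (median 0.75, adjusted p = 8.59e-05), with Dnajb1 at 1.65 ± 0.07 (0.0949 with an estimated correlation). Cytokines fell in 5 of 9 (6 adjusted over the list alone; adjusted p = 0.00178, and 0.127 with an estimated correlation), chemokines in 6 of 9 with 1 higher (7 lower adjusted over the list alone; adjusted p = 0.00197, and 0.0818 with an estimated correlation) and TLR genes in 7 of 14 with 2 higher (8 lower adjusted over the list alone; adjusted p = 0.0461, and 0.12 with an estimated correlation). Clock genes rose in 7 of 9 with 1 lower (adjusted p = 0.0477, and 0.24 with an estimated correlation). NF-kB targets did not pass, with 7 of 14 lower and 1 higher (median −0.18, 0.0856).

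The remaining liver lists did not pass with genipin after LPS. They were cholesterol synthesis (1 higher and 6 lower of 11, adjusted p = 0.0792), oxidative phosphorylation (3 of 25 higher, 0.286), endothelial activation (3 higher and 1 lower of 6, 0.336), tubule transporters (1 higher and 2 lower of 6, 0.385), the cell cycle (2 of 5 higher, 0.611) and acute-phase genes (2 of 17 lower, 0.669). The others were fatty acid oxidation (5 higher and 2 lower of 14, 0.698), tubule injury markers (2 higher and 2 lower of 7, 0.79), immediate early genes (7 higher and 7 lower of 16, 0.944), xenobiotic genes (9 higher and 6 lower of 23, 0.975) and glucocorticoid-responsive genes (4 higher and 2 lower of 12, 0.998). Of 2 cardiac genes 1 rose and 1 fell. The immediate early list had a median of −0.08 and a mean of 0.06, the xenobiotic list 0.08 and −0.04, and the glucocorticoid list −0.01 and 0.03. After adjusting within lists, 2 oxidative phosphorylation and 6 fatty acid genes were higher, 3 fatty acid, 1 acute-phase and 3 transporter genes were lower, and other counts were equal.

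In the LPS+genipin livers neutrophil markers fell in 3 of 3 (median −0.50) and fibroblast and pericyte markers rose in 4 of 5 (median 1.02). Macrophage markers were higher in 4 and lower in 3 of 10, endothelial markers higher in 2 (3 adjusted over the list alone), with Kdr at 2.23 ± 0.13, and lower in 3 of 8, and hepatocyte markers higher in 2 of 8. Both red blood cell, both neuronal and 2 of 3 skeletal muscle markers fell, as did the B cell, oligodendrocyte, podocyte and lung markers, 1 of 2 distal nephron (2 adjusted over the list alone) and 1 of 2 pancreatic acinar markers. Aif1 rose, and no astrocyte marker passed. The test called 4666 genes, 2531 higher and 2135 lower, with 718 at least 2-fold (419 lower) and 60.3% non-overlapping against 10% by chance.

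**Figure D2:**
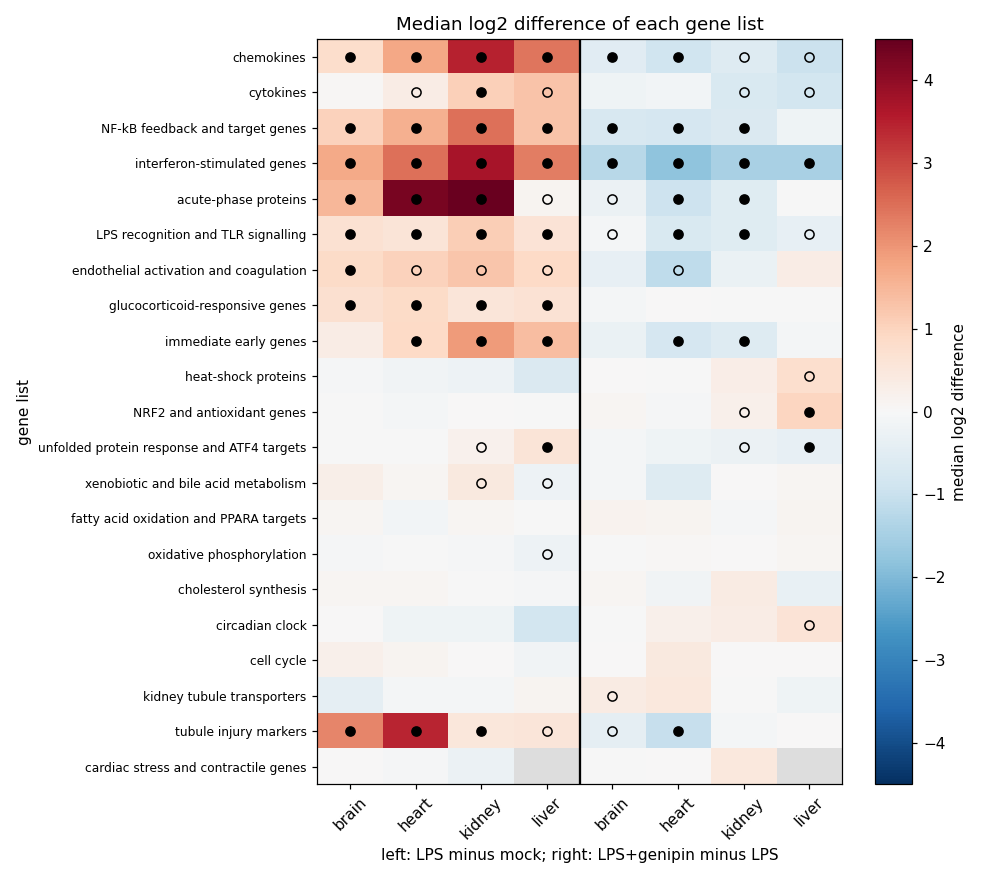
Median log2 difference of each gene list (vertical axis) in each tissue (horizontal axis), for LPS minus mock on the left and LPS+genipin minus LPS on the right, in red for higher and blue for lower. Filled circles mark lists that passed the camera test with the preset and the estimated correlation, open circles those that passed with the preset correlation only, and grey marks lists with fewer than 3 genes measured. Interferon-stimulated genes range from 1.70 to 3.71 on the left and from −1.83 to −1.23 on the right.

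Across tissues, 126 of 6861 genes were lower with genipin after LPS in every tissue, against 10.5 for independent lists, and 90 were higher in every tissue, against 24.1. Of the genes that LPS raised in every tissue, 94 were lower with genipin in every tissue, against 5.07 for independent lists, although both share the LPS arrays and are not independent. The 94 held 18 of 22 interferon-stimulated genes raised everywhere, 4 of 6 TLR genes, 4 of 6 immediate early genes, 3 of 9 NF-kB targets, 1 of 4 acute-phase genes and 1 of 2 chemokines, and none from the other lists. By the mean over tissues the smallest p belonged to Igtp (−1.98, a bound, as brain arrays with genipin lay at the floor), Rsad2 (−2.39 ± 0.04), Gbp2 (−2.29 ± 0.04), Isg15 (−2.25 ± 0.04), Gbp3 (−2.20 ± 0.05) and Cmpk2 (−1.85 ± 0.04), all induced by interferon. The mean called 4273 genes, 2498 higher and 1775 lower.

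The change with genipin differed among tissues for 5113 genes (74.5%), and 1546 genes passed in opposite directions in at least 2 tissues. Hspa1b rose in liver and kidney and fell in heart (−1.47 ± 0.07; F test adjusted p = 8.65e-23). Fasn (1.89e-22), Mybphl (8.65e-23) and Dkk3 (5.88e-21) differed mainly through the heart, where they had risen with LPS (3.82, 3.45 and 3.73) and fell with genipin (−3.48, −3.54 and −4.31), as did fat and atrial markers. Cmpk2 and the alarmin Il33 (both 5.88e-21) also differed. Icam1 fell in brain, heart and kidney and rose in liver (7.21e-16). The NRF2 list was 0.91 higher in liver than the mean of the other tissues (adjusted p = 0.00011) and −0.36 in heart (0.0053). Heat-shock proteins differed by 0.76 (0.000716) and NF-kB targets by 0.44 (0.00479) in liver, and immediate early genes by 0.48 in liver (0.00962) and −0.40 in heart (0.00109). These tissue differences passed with an estimated correlation, but without genes at the floor or at saturation NRF2 genes in heart (0.105) and heat-shock proteins in liver (0.118) did not.

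**Figure D3:**
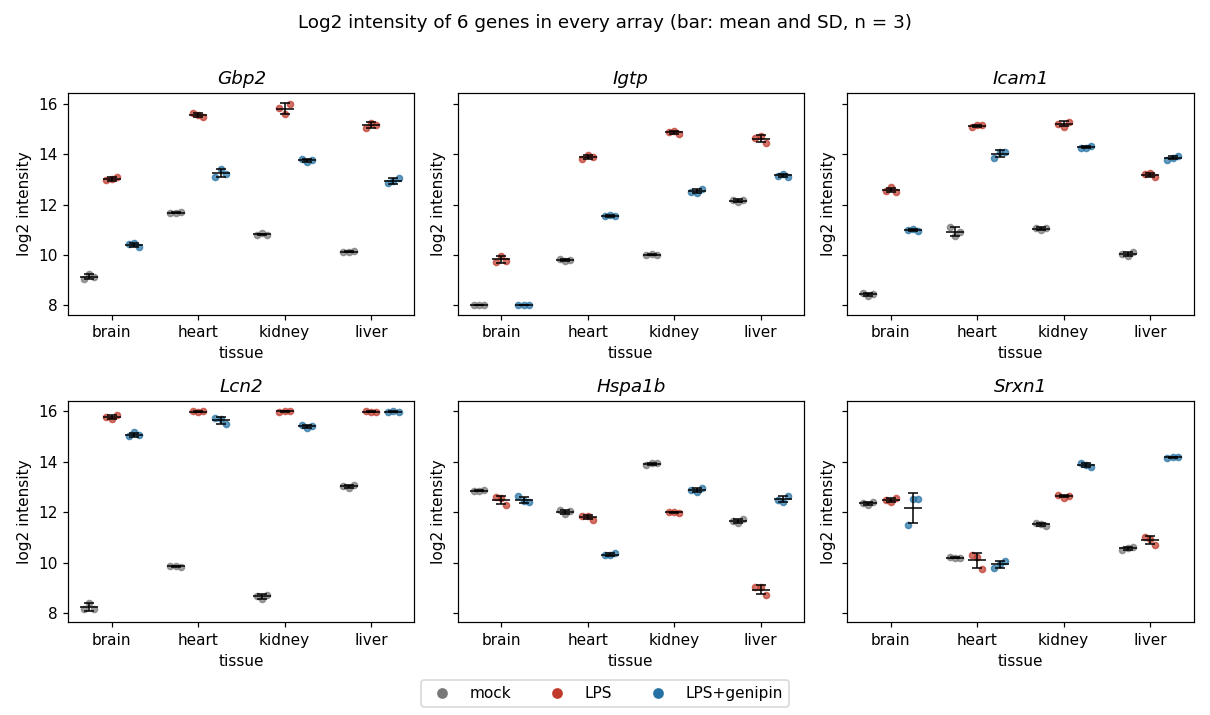
Log2 intensity of Gbp2, Igtp, Icam1, Lcn2, Hspa1b and Srxn1 (vertical axes) in every array of the 4 tissues (horizontal axis), coloured by treatment, with the mean and SD of 3 arrays. Levels are comparable within a tissue only; Gbp2 rose with LPS by 3.87 to 5.03 and was lower with genipin by −2.61 to −2.05.

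Along the LPS response, the LPS+genipin arrays lay between LPS and mock in each tissue. For genes at least 2-fold from mock, the change signed by the LPS response was −0.64 in brain (SD over LPS arrays 0.12), −0.93 in heart (SD 0.15), −0.76 in kidney (SD 0.01) and −0.54 in liver (SD 0.01). These amounted to −49.3, −67.7, −56.7 and −41.1% of an LPS change of 1.29, 1.37, 1.34 and 1.32. Of genes that LPS raised at least 2-fold, 126 of 164 in brain, 435 of 467 in heart, 432 of 517 in kidney and 493 of 691 in liver were lower with genipin, against 22.8, 92.6, 117 and 171 for independent lists. Of genes that LPS lowered at least 2-fold, 64 of 79, 206 of 225, 283 of 292 and 481 of 659 were higher with genipin, against 12.9, 49.7, 93.6 and 193. The lists share the LPS arrays and are not independent.

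Of the genes raised at least 2-fold by LPS, 128 in brain, 284 in heart, 446 in kidney and 544 in liver also passed above mock with genipin, against 14.4, 34.7, 104 and 195 for independent lists. Of those lowered, 59, 139, 240 and 570 passed below, against 4.44, 27.4, 70.6 and 212. These lists share the mock arrays. Lcn2 was 114-fold higher than mock in brain (6.83 ± 0.08), 55.7-fold in heart (5.80 ± 0.07), 107-fold in kidney (6.74 ± 0.05) and at least 7.80-fold in liver. Icam1 was higher by 2.55 ± 0.06, 3.09 ± 0.10, 3.22 ± 0.05 and 3.80 ± 0.07. Cxcl1 was higher by 6.20 ± 0.07 in heart, 7.06 ± 0.07 in kidney and 2.20 ± 0.04 in liver, and Tnf by 0.88 ± 0.19 in heart. Interferon-stimulated genes were higher than mock in 13 of 24 in brain (16 higher and 1 lower adjusted over the list alone; median 0.45, camera adjusted p = 4.94e-07), 25 of 29 in heart (26 adjusted over the list alone; 0.90, 4.64e-24), 26 of 27 in kidney (2.04, 1.15e-21) and 17 of 30 in liver with 5 lower (0.61, 0.000153), with the kidney and liver counts equal adjusted over the list alone. In liver the NRF2 list was higher than mock in 10 of 13 and lower in 1 (median 0.71, adjusted p = 0.000411), which became adjusted p = 0.0684 with an estimated correlation, and the counts were equal adjusted over the list alone. The tests called 1474 genes in brain (574 lower), 1895 in heart (1176 lower), 4248 in kidney (2323 lower) and 5220 in liver (2786 lower). The genes at least 2-fold from mock numbered 137, 157, 320 and 906.

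**Figure D4:**
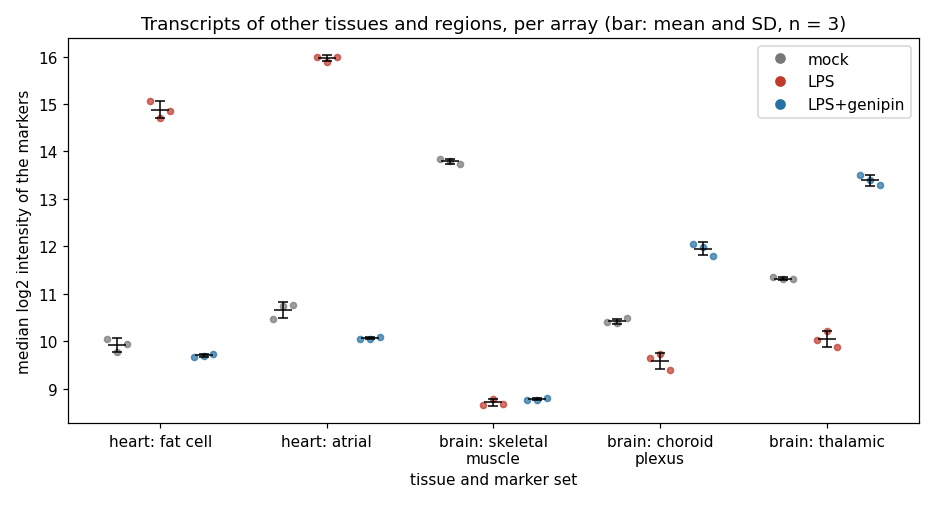
Median log2 intensity (vertical axis) of fat and atrial transcripts in heart and of skeletal muscle, choroid plexus and thalamic transcripts in brain (horizontal axis), in every array, with the mean and SD of 3 arrays. The sets were chosen after the data had been seen; the fat set lies at 14.7 to 15.1 in the LPS hearts against 9.68 to 10.0 in the other hearts, and the muscle set at 13.7 to 13.8 in the mock brains against 8.66 to 8.80 in the other brains.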

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

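The tests of fat, atrial, muscle, choroid plexus and thalamic markers, of a mislabelled array, of an LPS response in heart, of organs from 1 mouse and of a shared batch were chosen only after the result was seen.

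In the LPS hearts, 4 fat and 3 atrial transcripts stood far above the other hearts, with medians of 4.85 and 4.46 over mock. They were high in 3 of 3 LPS arrays, which argues against 1 mislabelled array. Markers that had not been seen to change were higher by a median of 0.90 for atrial muscle (SE 0.58, 3 markers; 1.58 over 4 with Mybphl) and of 0.72 for fat (SE 0.38, 12 markers; 0.81 over 13 with Fasn). More atrial or more fat tissue in the LPS samples stays open. So does an LPS response that genipin reversed, with −3.99% (SE 3.07, 7 genes) of the rise left in LPS+genipin hearts.

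In brain, 5 skeletal muscle transcripts were lower than mock by a median of −4.19 in the LPS arrays, and muscle markers that had not been seen to change were higher in mock by 1.41 (SE 0.55, 5 markers; 2.22 over 6 with Mss51), so that skeletal muscle in the mock samples may account for it. Thalamic markers that had not been seen to change differed by −0.70 (mock minus LPS, SE 0.32, 6 markers), or −0.59 over 7 with Zfhx3. Of the 7, 4 rose and 3 fell with LPS, so less thalamus in LPS brains stays open. The 6 were 0.81 higher with genipin. For choroid plexus markers the difference was −0.23 (mock minus LPS, SE 0.16, 5 markers), but only 2 of the 5 lay far enough above the floor in mock to show a fall, so less choroid plexus in the LPS brains stays open. No biological explanation was tested here.

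The spread between arrays of a group was small, and nothing says that the arrays are separate mice. Genes that respond to LPS varied no more between LPS arrays than other genes of like intensity (ratio 0.974, SE 0.0388 over 4 tissues; 1.04 in brain, 0.858 in heart, 0.986 in kidney and 0.962 in liver), so that the 3 arrays of a group may be repeats of 1 RNA pool. The p-values measure only the spread between arrays, which may be technical, and part of the overlap between comparisons may come from shared arrays. A batch shared by same-numbered arrays stays open, with a median correlation of 0.0639 (SE 0.0276, 54 pairs) over genes that LPS left alone, of 0.224 in the LPS arrays (0.0146 to 0.566, 18 pairs), 0.0317 in LPS+genipin and −0.0971 in mock. Whether same-numbered organs came from 1 mouse also stays open, with 0.268 (SE 0.0683, 18 pairs) over LPS-responsive genes; pairs share arrays, so these SEs are too small.

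Tested directly, the change with LPS differed among tissues for 5267 genes and that with genipin after LPS for 5113. Of 100 splits of the arrays within tissues, 1 (the real one) gave as many genes for each, with at most 3308 and 3247 in the others. The mean change with genipin over tissues (4273 genes) was matched by 1 of 100 with at most 1808 in the others. The splits mixed treatments within tissues, so they tested any treatment effect, not differences among tissues, mice or dissections, and ignored replicate numbers. For the tissue comparisons, 6 arrays allow 10 splits, too few for a share under 0.05. The real counts for LPS against mock were 3460, 4550, 6182 and 5704 in brain, heart, kidney and liver, with 0 as the highest other. For LPS+genipin against LPS they were 3085, 4053, 5262 and 4666, with 1, 0, 1 and 1 as the highest other (in brain 1 among the 4 splits that part 3 numbered pairs and 1 among the 6 that part 1), and for LPS+genipin against mock 1474, 1895, 4248 and 5220, with 0.

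Of the genes tested over all tissues, 702 were at the floor or saturated in at least 1 tissue under LPS, 546 of them among the 5267, and 638 under genipin, 462 of them among the 5113. Of the genes with the smallest p under LPS, the adjusted p was 2.27e-28 for Mylpf, 3.56e-25 for Lcn2 and Serpina3n, 1.44e-24 for Fcgr2b, 1.80e-24 for Arrdc3 and 3.16e-24 for Cmpk2. Under genipin it was 8.65e-23 for Hspa1b and Mybphl, 1.89e-22 for Fasn and 5.88e-21 for Cmpk2, Dkk3 and Il33. The panel genes Icam1, Lcn2 and Nfkbia had 5.95e-10, 3.56e-25 and 0.000121 under LPS and 7.21e-16, 1.63e-06 and 0.000456 under genipin. The p-values of Lcn2 rest on saturated arrays in heart, kidney and liver, those of Nfkbia (heart) and Serpina3n (heart and liver) partly on bounds, and they show no size of a tissue difference. Mylpf was a bound in liver only.

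The lists below differed between 1 tissue and the mean of the other 3, given as the median log2 difference. Under LPS, brain was lower for NF-kB targets (−0.63), interferon-stimulated genes (−0.98), TLR signalling (−0.30), immediate early genes (−1.50) and the unfolded protein response (−0.26), and heart was higher for acute-phase genes (0.24). Kidney was higher for NF-kB targets (0.75), interferon-stimulated genes (1.43), acute-phase genes (1.79), immediate early genes (0.71) and tubule injury markers (0.82). It was also higher for cytokines (0.46; adjusted p = 0.058 with an estimated correlation), endothelial activation (0.33; 0.194) and fatty acid oxidation (0.43; 0.054). Liver was lower for acute-phase genes (−1.64) and higher for the unfolded protein response (0.69). All 5 acute-phase genes were at a limit in at least 1 tissue, so that their values give no size. Without genes at a limit, TLR signalling in brain (adjusted p = 0.155) and fatty acid oxidation in kidney (0.0758) did not pass, and tubule injury markers were too few to test. The unfolded protein response, with no gene at a limit, then had 0.0571 in brain with an estimated correlation (0.0498 before), since fewer lists had a smaller p.

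With genipin after LPS, brain differed for interferon-stimulated genes (0.22; adjusted p = 0.0644 with an estimated correlation) and the clock (−0.48; 0.171). Heart differed for endothelial activation (−0.49; 0.171), immediate early genes (−0.40), heat-shock proteins (−0.28; 0.107), NRF2 genes (−0.36) and tubule injury markers (−0.84). Kidney differed for fatty acid oxidation (−0.38) and cholesterol synthesis (0.38; 0.0658). Liver differed for NF-kB targets (0.44), interferon-stimulated genes (−0.0703; 0.12), acute-phase genes (0.38; 0.0829), endothelial activation (1.16; 0.0832), immediate early genes (0.48), heat-shock proteins (0.76), NRF2 genes (0.91), the unfolded protein response (−0.17) and tubule injury markers (0.60; 0.058). Without genes at a limit, heat-shock proteins in heart (adjusted p = 0.0716) and the clock in brain (0.0881) did not pass, and acute-phase genes and tubule injury markers were too few to test. NRF2 genes in heart, heat-shock proteins in liver, fatty acid oxidation in kidney (median −0.87 over 5 genes) and the unfolded protein response in liver then passed with the preset correlation only (0.105, 0.118, 0.064 and 0.0571 with an estimated one). NF-kB targets in kidney (0.00821), NRF2 genes in brain (0.0053) and oxidative phosphorylation in heart (0.0289) passed only without genes at a limit, the last 2 with the preset correlation only (0.064 and 0.141 with an estimated one). The liver differences were then 0.73 for NF-kB targets and −0.23 for interferon-stimulated genes, which passed with an estimated correlation too (0.0428).

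Of probes without a gene symbol, not used above, 38 of 2432 in brain, 93 of 2349 in heart, 105 of 2114 in kidney and 151 of 1940 in liver were at least 2-fold higher with LPS, and 11, 27, 63 and 112 at least 2-fold lower.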

How the results depend on the processing

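The alternatives without a floor, without genes at a limit and with a random block in the tests of tissue differences were chosen only after the result was seen. Quantile normalization, centring, no floor and the mean of a gene's probes left all 19 counts and signed changes within their limits (1.5 times a count, 1 SD of a signed change), and limma with trend and robust variance all 15 counts. Blocking on the replicate number gave 3427, 3129 and 1449 genes in brain for the 3 comparisons and moved none of 15 counts beyond 1.5 times. For brain LPS+genipin against LPS, list and named-gene calls changed only where marked. Elsewhere within tissues, same-numbered arrays never all correlated over 0.1 (−0.550 to 0.289). Heart and liver LPS replicates 1 and 3 did with LPS+genipin 3 and 1 (0.502 to 0.610). Between tissues, same-numbered arrays of a treatment correlated over 0.1 in 27 of 54 pairs. A random block on treatment and number (consensus correlation 0.0934) gave 3923 genes for the mean over tissues and 5466 and 5323 for differences among tissues. Genes measured within limits in every tissue gave 3848, 4715 and 4649. Of 768 named values, 746 kept direction and side of the threshold with the replicate block. The mean of probes kept 760 and 1 fit over 36 arrays 745. With 1 array left out, 261 of their values lost the threshold, 1 gained it and 4346 did neither. Of 498 list member counts, 160 moved with the brighter 50% of genes, and 321 moved and 2667 did not with 1 array left out. Gfap in brain, LPS+genipin against LPS, reversed with the mean of probes (−0.0437 against 0.25); the cause was not tested.

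A 2-fold threshold leaves fewer genes by its construction, and gave, in the order LPS against mock, LPS+genipin against LPS and LPS+genipin against mock, 243, 167 and 137 in brain, 692, 479 and 157 in heart, 809, 439 and 320 in kidney, and 1350, 718 and 906 in liver. It gave 1624 and 1255 for differences among tissues and 66 for the mean. The brighter 50% of genes, which tests fewer genes, gave 1512, 1209 and 471 in brain, 2623, 2322 and 1020 in heart, 3012, 2448 and 2339 in kidney, and 3063, 2349 and 2853 in liver. It gave 2677 and 2532 for differences among tissues and 2037 for the mean, with signed changes of −0.79 in kidney and −0.51 in liver. A floor at the 25th percentile gave 979 in brain for LPS+genipin against mock and −0.51 for the liver signed change, and every probe −0.57 for the latter. The 1 fit over 36 arrays gave 2848 in heart for LPS+genipin against mock; the cause was not tested. Genes at least 4-fold from mock gave signed changes of −0.94, −1.72, −1.18 and −0.88 in brain, heart, kidney and liver. Fat and atrial transcripts were again included in heart and muscle transcripts in brain. With an estimated correlation 80 list tests passed in place of 121.

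Leaving out 1 array lowers the number of arrays. In the same order, counts ranged over 2261 (without mock replicate 3) to 3715, 2139 to 3249 and 852 (without mock replicate 1) to 1192 in brain. In heart they ranged over 3904 to 4247, 3134 to 4000 and 1204 (without LPS+genipin replicate 2) to 1504. The ranges were 5562 to 5951, 4611 to 4997 and 3615 to 3904 in kidney, and 5065 to 5625, 3940 to 4585 and 4638 to 4863 in liver. In brain, LPS+genipin against mock also moved by over 1.5 times without mock replicate 2 (952), mock replicate 3 (864) or LPS+genipin replicate 2 (917). In heart the same comparison did so without mock replicate 2 (1256) or LPS+genipin replicate 1 (1205). Differences among tissues ranged over 4731 to 5090 and 4493 to 4934, the mean over 3850 to 4260, and signed changes over −0.67 to −0.58 in brain, −1.02 to −0.90 in heart, −0.80 to −0.73 in kidney and −0.59 to −0.50 in liver.

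Probes dimmer than the floor of 263 and those above 60000 give bounds only.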

Other observations

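The longer marker lists were chosen only after the result was seen, and the values below are medians over markers that had not been seen to change, for LPS minus mock and then LPS+genipin minus LPS. Fat markers gave 0.19 and −0.01 in brain (12 markers), 0.72 and −0.58 in heart (12), 0.19 and 0.19 in kidney (13) and 0.38 and −0.41 in liver (11). Atrial markers gave 0.29 and 0.00 in brain (3), 0.90 and −1.03 in heart (3), 0.17 and 0.03 in kidney (2) and −0.23 and 0.14 in liver (2). Skeletal muscle markers gave −1.41 and 0.34 in brain (5), −0.05 and 0.00 in heart (7), 0.00 and 0.29 in kidney (5) and 0.85 and −0.60 in liver (4).

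Choroid plexus markers gave 0.23 and 0.65 in brain (5), −0.29 and −0.19 in heart (3), −0.07 and −0.02 in kidney (8) and −0.08 and −0.10 in liver (3). Thalamic markers gave 0.70 and 0.81 in brain (6), −0.04 and 0.12 in heart (7), 0.06 and 0.16 in kidney (5) and −0.16 and −0.30 in liver (5).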
